A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

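The series holds 4 two-channel arrays of budding yeast (Saccharomyces cerevisiae) RNA, each setting cDNA from RNA precipitated with zz-tagged Mex67 against cDNA from RNA precipitated with the zz tag alone, per the labels. The 4 arrays form 1 group and were numbered replicates 1 to 4 in accession order, so the number only names an array. Replicate 1 stands in a table of its own with 7680 spots, and replicates 2, 3 and 4 share a second table of another platform with 12800 spots. The sample titles carry a different date on each array without saying which step it marks, so no date holds more than 1 array. Slide and scan numbers were slide 1 and scan 1 for replicate 1, slide 5 and scan 3 for replicate 2, and slide 3 and scan 3 for replicates 3 and 4. Nothing in the labels says that the arrays came from separate cultures or precipitations. Limma's p-values for single genes then measure only the spread between these arrays, which may be technical.

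The deposited values are log10 ratios of the 2 channels of an array. The log base was read from the values: 10 to the power of the value was a fraction with a denominator of at most 50, within a tolerance of 2e-08, for 0.276%, 4.68%, 15.6% and 13.3% of the spots of replicates 1 to 4. With base 2 the shares were 0%, 0%, 0.130% and 0.0222%. The spot medians of the deposited log10 ratios were 0.386, -0.163, -0.251 and 0.643, so the authors' values had not been centred on a common value. Which channel is the numerator, the dyes, the scanner settings, the background correction, any normalization within an array and the reason why many spots carry no value are not given in the sources used here. The files give no intensities, so a filter on dim spots was not run and random lists of genes were not matched on brightness.

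Values were converted to log2 and all spots of a gene were averaged, a step chosen after it was seen that most genes of the second table are printed as neighbouring duplicates. Each array was then centred on the median of its genes, with no loess or quantile step. Gene symbols came from the platform annotation, were checked through gene identifiers against a RefSeq gene table (assembly R64), and needed 0 updates. On the first platform 6695 spots named 1 gene and 985 named none. On the second platform 11138 named 1 gene and 1662 none, and no spot named several. The gene identifiers of 5 and 10 spots were not found in the reference table and kept the annotation's symbol. Spots without a gene name were left out. No coordinates are given because the files name no genome build.

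The sign of replicate 2, on which the labels put the zzMex67 precipitate in channel 2, was turned before any fit, and leaving it as deposited was an alternative. The design, the alternatives listed first, the rule for named genes and 26 gene lists were fixed before the data were examined. The test was limma's lmFit and eBayes with an intercept, on the genes measured on all 3 arrays of the second table, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes at 2-fold or more with the same sign on all 3 arrays were counted against 10000 shuffles of the gene labels within arrays. Gene lists with at least 3 measured members were tested with limma's camera, with a preset correlation of 0.01 and with an estimated correlation. With the preset correlation the p-value sets a list's genes against the spread over genes, treats them as nearly independent, and does not measure the spread between arrays. With an estimated correlation the degrees of freedom come from the few arrays, which leaves little power to call a list. On single arrays a list's median was ranked among 10000 random lists of the same size. The difference between the correlations of duplicate spots and of neighbouring spots was given an interval from 1000 bootstrap draws of runs of 400 spots. Correlations between arrays are across genes, which are not independent replicates, and carry no p-value. The design's test used the second table alone, because the tables come from different platforms. The alternatives on all 4 arrays and on replicates 1, 3 and 4 join the tables by gene. Of the 26 lists, 23 had at least 1 named member on the arrays. The lists of mitochondrially encoded genes, stable noncoding RNAs and Ty transposon ORFs matched 0 gene symbols.

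The rule for named genes took, in each direction, the 12 genes with the largest mean among those past the test with the same sign on every array. Where fewer than 12 passed, it was filled with genes of the same sign on all 3 arrays by their smallest value in size. It also took, in each list, the 2 members with the same sign on all 3 arrays and the largest mean, and always MEX67, MTR2, YRA1, NPL3, SUB2, NAB2, URA3, LEU2, HIS3, TRP1 and ADE2. Other genes named in the text were chosen after their values were seen.

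Alternatives fixed in advance were the sign of replicate 2, no centring, scaling to a common median absolute deviation, quantile normalization, a dye term, all 4 arrays joined by gene, genes on at least 2 of the 3 arrays, a robust prior, leaving out each array, a 1.5-fold threshold, and rank-based camera. Alternatives added after the data were seen were centring each run of 400 consecutive spots on its own median (runs with at least 10 values), the 3 arrays of one channel order, replicates 3 and 4 alone, all 4 arrays with no sign turned, and spots not averaged.

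The steps were tested on simulated data. With 135 genes, 3 arrays and an SD of 1.90, limma recovered 0.75% of genes shifted 2-fold, 4% at 4-fold, 68% at 16-fold and 99.25% at 64-fold, with 20 shifted genes in each of 20 runs. Camera called a list of 29 of the 135 genes in 98 of 100 runs with a log2 shift of 1, and in 1 of 100 with none. The simulated genes were independent, whereas the estimated correlation of the 29 ribosomal protein genes was 0.559 on the 3 arrays. These camera rates therefore need not hold for the data. Lists of 3 members and camera with an estimated correlation were not simulated. The shuffle count was past 0.05 in 50 of 50 runs with 20 genes shifted by 4 on the log2 scale, and in 2 of 50 with no shift. The number of arrays limits the precision. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.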

Results

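Mex67 is the receptor that carries messenger RNA through the nuclear pore in budding yeast. RNA that came down with zz-tagged Mex67 was set against RNA that came down with the zz tag alone, an immunoglobulin-binding tag derived from protein A, and both were hybridised to the same array. The comparison asks which RNAs are found with the export receptor beyond what the tag brings down. There were 4 such arrays, all of 1 group. Replicate 1 was measured on one platform and had values on 5800 of 7680 spots (75.5%), covering 4409 named genes. Replicates 2, 3 and 4 were measured on a second platform of 12800 spots and had values on 1004 (7.84%), 4610 (36.0%) and 4498 (35.1%), covering 524, 2280 and 2421 genes. Only 135 genes had a value on all 3 arrays of the second platform, 725 on replicates 1, 3 and 4, and 119 on all 4.

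All values are log2 ratios minus the array's median over genes. A higher ratio likely means more RNA in the zzMex67 precipitate, because the sample titles name that precipitate first and channel 1 holds it on replicates 1, 3 and 4. The deposited files do not settle this direction, so ratios are called higher or lower and not enriched. On replicate 2 the labels put the zzMex67 precipitate in channel 2. Its values are given with the sign turned where arrays were combined, and as deposited where stated.

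Messenger RNAs of the cytosolic ribosomal proteins and of the glycolytic enzymes had medians above that of all genes on each of the 3 arrays of one channel order, replicates 1, 3 and 4. On replicate 1 the 135 measured ribosomal protein genes had a median of 3.38 (SD over members 1.52), which is 10.4-fold above the array median, and 124 of them lay above it. Their medians were 0.59 (SD 1.75, 84 genes) on replicate 3 and 0.85 (SD 1.85, 77 genes) on replicate 4, or 1.505-fold and 1.804-fold. The glycolysis and fermentation genes had medians of 3.34 (SD 1.48, 24 genes), 1.45 (SD 1.15, 12 genes) and 1.75 (SD 1.43, 17 genes) on the same arrays, or 10.1-fold, 2.73-fold and 3.36-fold. The ribosomal protein medians ranked above 99.68% of random lists or more on these 3 arrays, and the glycolysis medians above 98.67% or more.

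Across replicates 1, 3 and 4, a combination that joins the 2 platforms by gene and was chosen after the data were seen, 8 of 10 glycolysis genes and 23 of 49 ribosomal protein genes lay above the median on every array, against 139 of all 725 genes (19.2%). The enolase genes ENO1 (4.67, 2.74 and 2.49 on replicates 1, 3 and 4) and ENO2 (4.50, 1.90 and 2.57), the alcohol dehydrogenase gene ADH1 (4.06, 1.91 and 1.75) and the glyceraldehyde-3-phosphate dehydrogenase gene TDH3 (4.87, 0.61 and 3.12) were among the 8. The ribosomal protein genes RPL24A (5.18, 4.86 and 2.75) and RPS1A (5.58, 1.48 and 3.36) were among the 23. ADH4, at 3.32, -0.82 and -0.45, and RPS17A, at 3.99, -3.47 and -0.97, were exceptions. With limma's camera and the preset correlation, 3 of 14 lists passed on these arrays. The shift against other genes was 1.502 for 49 ribosomal protein genes (adjusted p = 2.33e-13), 1.85 for 10 glycolysis genes (adjusted p = 4.03e-06) and 1.54 for 6 translation factor genes (adjusted p = 0.00422). None of the 3 calls held with an estimated correlation (limma's camera, adjusted p = 0.805 for each). That version takes its degrees of freedom from the 3 arrays and has little power, so it does not decide against the lists. The preset p-values do not measure the spread between arrays. The estimated correlations of the 3 lists were 0.435, 0.440 and 0.267, above the preset 0.01. On replicates 3 and 4 alone the shifts were 0.78, 1.22 and 1.05 (49, 10 and 7 genes, limma's camera, adjusted p = 0.00625, 0.0264 and 0.171, and 0.999 for each with an estimated correlation), which ends the translation factor call. No single gene among the 725 passed limma's test over all genes, against 65 at an unadjusted p under 0.05. Adjusted over the list alone, 6 of the 10 glycolysis genes, 4 of the 6 translation factor genes and 1 of the 49 ribosomal protein genes passed. So did 1 of 4 chaperone genes and 1 of 9 mitochondrial ribosomal protein genes, whose lists did not pass. On replicates 3 and 4 alone, 0 of 10, 0 of 7 and 0 of 49 genes of the 3 lists passed in this way. There 1 of 4 chaperone and 2 of 12 mitochondrial ribosomal protein genes did. Members of these families are near-identical in sequence (TDH2 and TDH3, TEF1 and TEF2, most ribosomal protein pairs), and the probes may not tell them apart.

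**Figure D1:**
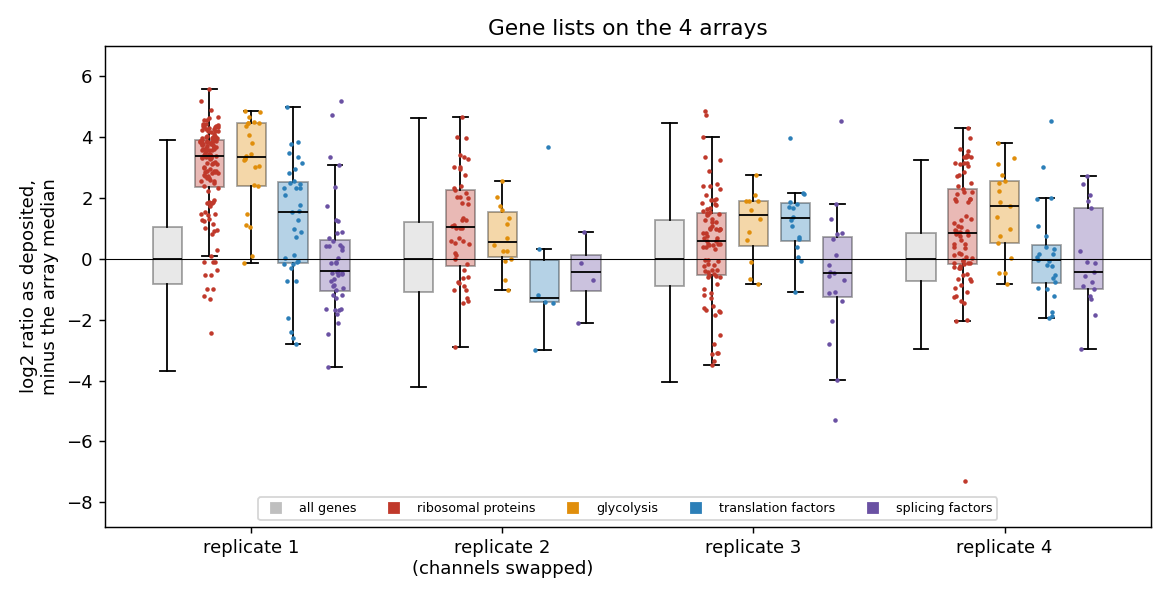
Log2 ratio as deposited minus the array median (vertical axis) on replicates 1 to 4 for all genes (grey) and for the members of 4 gene lists, with points for genes, boxes from the lower to the upper quartile, a line at the median, and whiskers to the farthest value within 1.5 box lengths. Ribosomal protein genes have medians of 3.38, 1.04, 0.59 and 0.85, and replicate 2, with swapped channels, is drawn without turning its sign.

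On replicate 2, the medians of the ribosomal protein and glycolysis genes lay below the array median once the sign was turned, with 13 of 48 and 3 of 14 genes on the other side. As deposited, its 48 ribosomal protein genes had a median of 1.04 (SD 1.70), above 99.98% of random lists, which becomes -1.04 when the sign follows the channel labels and was 0.23, above 92.67% of random lists, after each run of 400 neighbouring spots was centred. Its 14 glycolysis genes had a deposited median of 0.56 (SD 1.05), above 84.97% of random lists and so within their middle 95%. Its 6 translation factor genes went the other way, with a deposited median of -1.29 (SD 2.30), above 4.03% of random lists. On the 3 arrays of the second platform, the direction of the ribosomal protein list therefore depends on a sign that the files do not settle, while all 4 arrays gave a shift of 0.20 with the sign turned and 0.70 with none turned.

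On the 3 arrays of the second platform, the design's test, 0 of 6 lists passed limma's camera. The 3 translation factor genes had a mean of 1.62 against 0.55 for the other genes (shift 1.07, adjusted p = 0.197), and 3 intron-containing genes outside the ribosomal proteins a mean of 1.81 against 0.55 (shift 1.26, adjusted p = 0.183), in limma's camera. On replicates 1, 3 and 4 the intron-containing list had 12 members and a shift of 0.25. The 9 glycolysis genes had a mean of 0.99 against 0.54 (shift 0.45, limma's camera, adjusted p = 0.393), and leaving out replicate 2, 3 or 4 gave shifts of 0.87, 0.26 and 0.21. The 29 ribosomal protein genes had a mean of 0.41 against 0.62 (shift -0.21, limma's camera, adjusted p = 0.413). Of these, 5 had a higher ratio on all 3 arrays and 2 a lower one. Shifts were -0.60 for 3 cell wall genes and -0.33 for 3 amino acid biosynthesis genes. The cell wall list did not hold CCW22, a cell wall protein gene described below, and each of these shifts describes only its 3 members. With an estimated correlation the smallest adjusted p from limma's camera was 0.755. In each of the 6 lists, 0 members passed limma's test over all genes and 0 when adjusted over the list alone. With replicate 2 as deposited, the ribosomal protein shift was 0.46 and the glycolysis shift 0.72 (limma's camera, adjusted p = 0.115 for both), while the translation factor shift turned to -0.39 and the amino acid biosynthesis shift to 0.49, and the cell wall and intron-containing shifts were -1.11 and 0.74. With a dye term, fixed in advance, the shifts were 1.35 for translation factors, 1.14 for intron-containing genes and 0.23 for glycolysis. They were -0.41 for ribosomal proteins, -0.56 for amino acid biosynthesis and -0.26 for cell wall genes (limma's camera, smallest adjusted p = 0.130).

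Gene by gene, TEF2, DBP2, YJR029W and UPS3 had the highest mean ratios over the 3 arrays of the second platform, and no gene passed the test. TEF2 (YBR118W), which with TEF1 (YPR080W) encodes translation elongation factor 1 alpha, had a mean of 2.59 ± 1.69 (SD, n = 3), or 6.03-fold, with 4.53 on replicate 4 far above the others and a mean of 1.62 without it. TEF1 had 1.96 ± 0.95 (SD, n = 3). DBP2 (YNL112W), an RNA helicase gene, had 2.504 ± 2.087 (SD, n = 3), with 4.91 on replicate 4, a mean of 1.30 without that array, and -0.39 on replicate 1. ASC1 (YMR116C), whose product binds the small ribosomal subunit, had 1.64 ± 0.36 (SD, n = 3). The ribosomal protein genes RPL20B (YOR312C) and RPL27A (YHR010W) had 1.64 ± 0.67 and 1.76 ± 1.48 (SD, n = 3). Limma's test called 0 of 135 genes, with 6 at an unadjusted p under 0.05, all with a higher ratio, and a smallest adjusted p of 0.6998. The test is against the median of all genes of an array. The 135 genes themselves had medians of 0.64 and 1.31 on replicates 3 and 4, and -0.15 on replicate 2 (turned). Part of a higher mean is therefore shared by the genes tested.

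The genes of the same sign on all 3 arrays, all below the threshold, numbered 34 with a higher ratio and 4 with a lower one. Independent signs, with each array's own share of genes above 0, give 33.1 and 4.57. Among those taken by the naming rule, the Ty1 transposon ORFs YML039W, YJR029W and YBR012W-B had means of 1.66 ± 0.26, 2.44 ± 1.72 and 1.55 ± 1.19 (SD, n = 3), and such ORFs exist in many near-identical copies. Of other Ty ORFs on these arrays, recognised after the values were seen, YCL019W had 1.09 ± 0.74 and YER160C 0.81 ± 0.50 with 1 sign, while YAR009C (1.10 ± 1.40) and YJR027W (-0.20 ± 2.01, with -2.502 on replicate 3) had mixed signs (SD, n = 3). CCW22 (YDR134C), a cell wall protein gene, had 1.99 ± 0.79 and UPS3 (YDR185C), a mitochondrial protein gene, 2.36 ± 1.00 (SD, n = 3). CWC21 (YDR482C), which encodes a spliceosome component, had 1.38 ± 0.88, and the asparaginase gene ASP3-1 (YLR155C) 1.94 ± 1.96 (SD, n = 3). From the lists, TDH2 (YJR009C) had 1.21 ± 1.08, the acetolactate synthase gene ILV2 (YMR108W) 1.36 ± 1.00, the ATP synthase gene ATP2 (YJR121W) 1.14 ± 0.42, the superoxide dismutase gene SOD2 (YHR008C) 0.81 ± 0.44 and the nucleoporin gene NUP53 (YMR153W) 0.23 ± 0.18 (SD, n = 3). The 4 lower genes were RPS17A (YML024W) at -2.08 ± 1.27, CSN9 (YDR179C), a signalosome subunit gene, at -1.44 ± 0.55, PCL8 (YPL219W), a cyclin gene, at -1.12 ± 1.30, and the ribosomal protein gene RPP1A (YDL081C) at -0.41 ± 0.51 (SD, n = 3). Adjusted p-values from limma were between 0.6998 and 0.965 for all of these genes. PCL8, RPP1A and NUP53 change sign when replicate 2 is left as deposited. Leaving out 1 array lowered several of these means in size by over 1.5 times. Without replicate 4 they were 0.96 for RPL27A, 0.80 for ASP3-1, 0.86 for YBR012W-B, 0.69 for TDH2 and 0.87 for ILV2. Without replicate 3 they were 0.87 for CWC21 and 1.49 for YJR029W, and without replicate 2 they were -0.38 for PCL8, -0.12 for RPP1A and 0.13 for NUP53. On replicate 1, CWC21 had -2.84, RPL27A -0.36 and RPS17A 3.99.

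Large ratios shared by all 3 arrays of the second platform were no more frequent than in shuffled data. At 2-fold or more, 7 genes had a higher ratio on all 3 arrays, TEF2, UPS3, YML039W, CCW22, ASC1, DBP2 and TEF1, and 0 had a lower one. Shuffling gene labels within arrays gave 6.53 higher genes on average (the middle 95% of shuffles from 3 to 11) and 0.315 lower ones. The share of 10000 shuffles with as many genes was 0.486 for higher ratios and 1 for lower ones. The 135 genes had medians of -0.15, 0.64 and 1.31 on replicates 2, 3 and 4, since the genes measured on every array are not centred on the median of all genes of an array. With replicate 2 as deposited the count was 11, where shuffles gave 9.82 on average. Over replicates 1, 3 and 4, chosen after the data were seen, it was 39 of 725 genes (35 higher and 4 lower), or 5.38% against 5.19% of the 135, and shuffles gave 27.7 on average (the middle 95% from 19 to 37, share with as many 0.0134).

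Of the genes always named, those of the export pathway were measured on few arrays and had no common direction. MEX67 had 0.11 on replicate 1 and -0.40 on replicate 4, and MTR2, the gene of its partner subunit, -0.74, 2.68 and 0.34 on replicates 1, 3 and 4. The export adaptor gene YRA1 had 1.22 and -1.57 on replicates 1 and 3, and the helicase gene SUB2 2.26 on replicate 3. NPL3, which encodes an mRNA-binding protein, had -0.81, 0.40 and 0.16 on replicates 1, 3 and 4. NAB2, the gene of a poly(A)-binding protein, had -0.72 and 0.11 on replicates 1 and 4. Over the list of mRNA export and packaging factors the medians were 0.10 (22 genes), 0.26 (16 genes) and -0.15 (18 genes) on replicates 1, 3 and 4, within the middle of random lists. DBP2, also on this list, had -0.39 on replicate 1 and 1.21 (sign turned), 1.39 and 4.91 on replicates 2, 3 and 4. The list's shift was 0.78 on replicates 1, 3 and 4 (5 genes, limma's camera, adjusted p = 0.343). It was 0.61 on replicates 3 and 4 alone (7 genes, limma's camera, adjusted p = 0.554), where 5 lay above the median on both arrays and 1 below. Among the marker genes that strains and plasmids can differ in, HIS3 had 4.55 on replicate 1 and a mean of 0.43 ± 1.21 (SD, n = 3) on the second platform. URA3 and ADE2 had -1.23 and 1.73 on replicate 1, LEU2 0.71 and 1.18 on replicates 1 and 4, and TRP1 -1.70 and -0.96 on replicates 1 and 3.

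Replicate 1, the single array of the first platform, had 8 of 23 ranked lists above the middle 95% of random lists and 0 below it, or 8 and 1 with runs of 400 spots centred. Of its 100 highest genes, 24 encoded ribosomal proteins, 8 glycolytic or fermentative enzymes and 6 cell wall proteins, where these lists held 135, 24 and 48 of its 4409 measured genes. Its list medians were also high for hexose transporters (1.67, SD 1.25, 16 genes), translation factors (1.53, SD 1.96, 35 genes), cell wall proteins (1.04, SD 2.10, 48 genes), ergosterol enzymes (1.02, SD 1.87, 21 genes) and proteasome subunits (0.85, SD 2.14, 30 genes), each above 99.33% of random lists or more. The intron-containing genes outside the ribosomal proteins had 0.39 (80 genes, above 97.6% of random lists), and 0.29 with runs centred (above 94.51%). On the second platform cell wall genes had medians of 0.30 on replicate 3 and 0.07 on replicate 4, and hexose transporters had -0.19 and 0.18. Translation factor genes had 1.33 on replicate 3 (16 genes, above 99.06% of random lists) and -0.04 on replicate 4 (24 genes). This array has no replicate on its platform, and over the 119 genes on all 4 arrays it had a correlation of -0.005 with the mean of the other 3 (Spearman's rho 0.019), or 0.048 with no sign turned (rho 0.134).

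**Figure D2:**
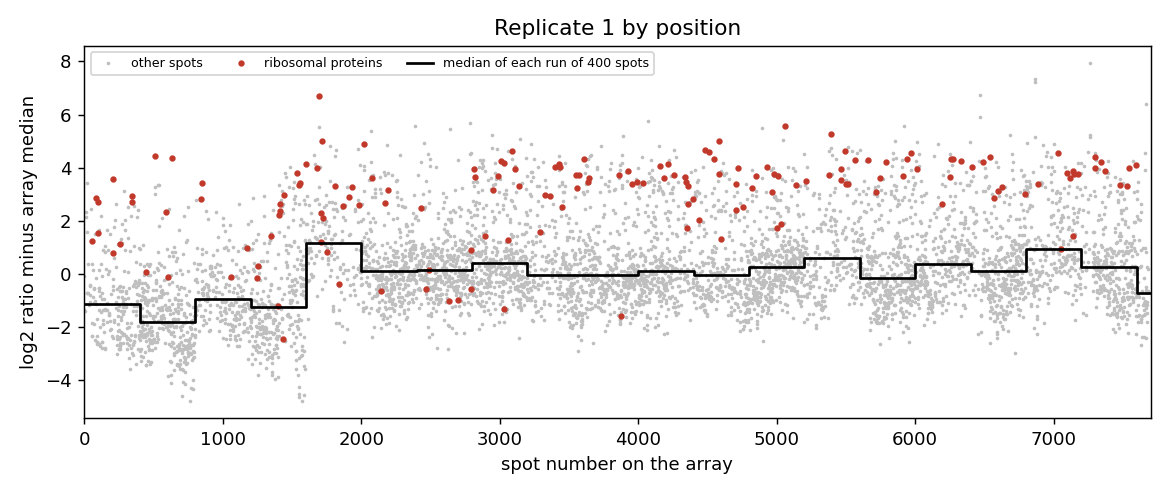
Log2 ratio minus the array median (vertical axis) of every measured spot of replicate 1 by its spot number on the array (horizontal axis), with ribosomal protein spots in red and the median of each run of 400 spots as a black line. Run medians lie between -1.80 and 1.17, and ribosomal protein spots lie above them over most of the array.

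Gene by gene, ratios on different arrays hardly correlated. Across all genes measured on both arrays, the correlation was -0.018 between replicates 3 and 4 (923 genes, rho -0.013), 0.060 between 1 and 3 (1777 genes, rho 0.061), and 0.084 between 1 and 4 (1912 genes, rho 0.084). Replicate 2, as deposited, had correlations of 0.029, -0.012 and 0.114 with replicates 1, 3 and 4 (442, 222 and 337 genes; rho 0.042, -0.017 and 0.126), which turn their sign with it. Without the ribosomal protein and glycolysis genes the correlations were -0.037 between 3 and 4, 0.039 between 1 and 3, and 0.034 between 1 and 4. Duplicate spots of a gene on the same array had correlations of 0.798, 0.760 and 0.866 on replicates 2, 3 and 4 (358, 1773 and 1463 pairs). Neighbouring spots of different genes had 0.396, 0.589 and 0.670. Runs of 400 spots took 16.5%, 26.0%, 33.8% and 16.1% of the variance on replicates 1 to 4.

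**Figure D3:**
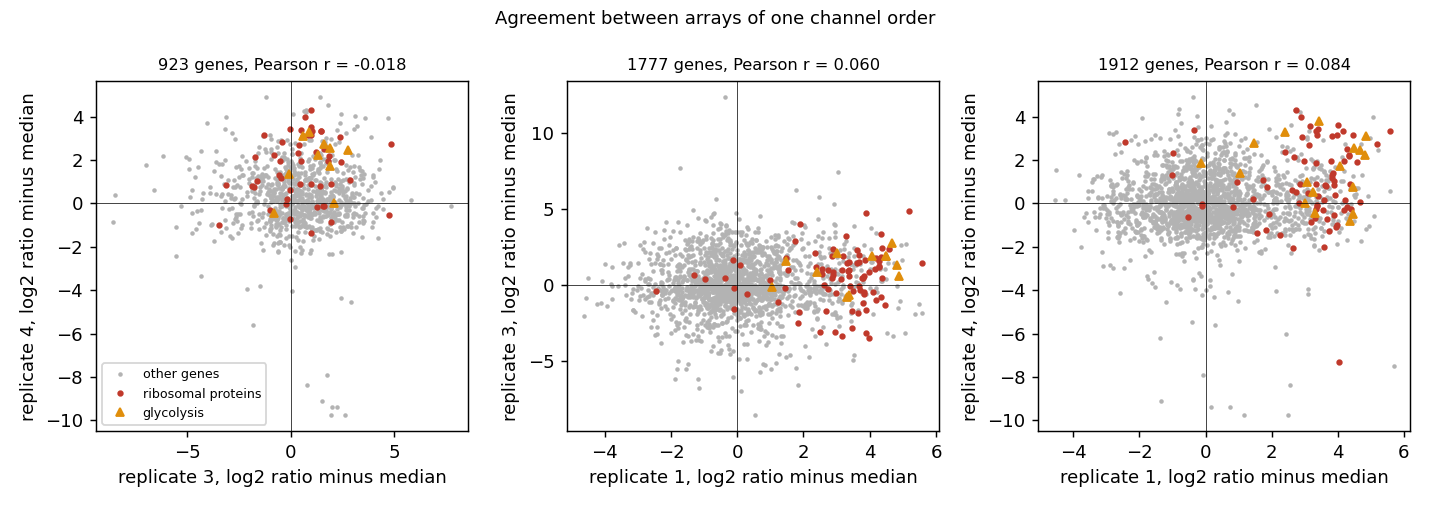
Log2 ratios minus the array median of genes measured on both arrays of a pair, for replicates 3 and 4, 1 and 3, and 1 and 4, with ribosomal protein genes as red points and glycolysis genes as orange triangles. Pearson's r across all genes is -0.018, 0.060 and 0.084, while most red and orange symbols lie to the right of 0 on replicate 1.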

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

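The test of position against the correlation of replicates 3 and 4, and that of chromosome IV, were set before their results were seen, and the other tests here were chosen after. Of 38 array properties, list medians and genes with a value on all 4 arrays, 4 had 1 array far from the other 3. At 1 in 20, chance gives 1.9, but most of the genes were chosen for 1 sign on 3 of the arrays, which may change that rate. The translation factor list had -0.0405 on replicate 4, against 1.53, 1.29 (turned) and 1.33 on replicates 1 to 3. The splicing factor list had 0.41 on replicate 2 with its sign turned, against -0.41, -0.45 and -0.44 on replicates 1, 3 and 4, and -0.41 on replicate 2 as deposited. TEF2 had 4.53 on replicate 4, against 1.53, 1.44 (turned) and 1.81. PCL8 had -2.61 on replicate 2 with its sign turned, against -0.29, -0.19 and -0.58.

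As deposited, the ribosomal protein genes had medians above the array median on all 4 arrays, although 11 of 135, 13 of 48, 33 of 84 and 25 of 77 genes lay below it on replicates 1 to 4, and of those measured on every array 12 of 29 lay above on each, against 32 of all 119 genes. With the sign of replicate 2 turned, 4 of the 29 lay above on each, against 21 of the 119 genes. With each run of 400 spots centred, the list had medians of 3.25, 0.62 and 0.50 on the 3 arrays of one channel order. It stayed above 95% of random lists on 3 of the 3, which argues against position on the scale of such runs as the whole cause there. These runs took 16.5%, 33.8% and 16.1% of the variance on replicates 1, 3 and 4, and random lists were not matched on position. The test cannot decide on position effects finer than a run, which may remain. On replicate 2 the median dropped from 1.04, above 99.98% of random lists, to 0.23, above 92.67% and so within the middle 95%, and position may account for most of it on that array. A dye or brightness bias and more of these RNAs in one precipitate cannot be told apart: the only swapped array is the one that position affects in this way, and the labels leave open whether its sign had been turned before deposit.

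Arrays hardly correlated across genes, although duplicate spots of an array did. The duplicate correlation exceeded that of neighbouring spots of different genes by 0.402, 0.171 and 0.196 on replicates 2, 3 and 4 (95% bootstrap intervals over runs of 400 spots 0.301 to 0.699, 0.130 to 0.261 and 0.136 to 0.297), which is beyond the 0.1 that position alone was allowed and argues against it as the whole cause. The stricter bound set first, 0.2 on all 3 arrays, was not met, and the intervals were added after the excesses were seen. Neighbours also correlated, so position may be part of it, and a bias tied to the printed DNA or its brightness was not tested. Position on the scale of runs of 400 spots hiding a strong common signal is argued against by the correlation of replicates 3 and 4. Centring each run took it from -0.018 to 0.0588, under the 0.2 set in advance for such hiding. The correlations of replicate 1 with replicates 3 and 4 went from 0.060 to 0.079 and from 0.084 to 0.095. A weak common signal may therefore have been hidden in part. Such runs took 33.8% and 16.1% of the variance on these arrays, while neighbouring spots of different genes had correlations of 0.589 and 0.670. Position effects finer than a run may therefore remain, and the test cannot decide whether those hide a common signal. No biological explanation was tested.

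Of the 100 lowest genes of replicate 1, 56 lie on chromosome IV by systematic name, where 514 of the 4409 measured genes lie. Position is a candidate explanation: 98 of the 100 have a spot in the first 1600 positions, which hold all 515 measured chromosome IV spots. In that part of the array the 468 spots of other chromosomes had a median of -1.16, against -1.34 for chromosome IV, as position predicts. After centring each run of 400 spots, 18 of the 100 lowest genes were on chromosome IV. No biological explanation was tested, and the chromosome's medians on replicates 2 (as deposited), 3 and 4 were 1.00, -0.24 and 0.19.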

How the results depend on the processing

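The alternatives on other sets of arrays, on position and on unaveraged spots were chosen after the data were seen. Limma called 0 genes in every setting run, with 3 to 65 genes at an unadjusted p under 0.05. The count of genes at 2-fold or more on every array, 7 of 135, was 11 with replicate 2 as deposited, 18 at 1.5-fold, 19 of 232 unaveraged spots, 39 of 725 genes on replicates 1, 3 and 4, 117 of 923 on replicates 3 and 4 alone (126.9 in shuffles), and 16 to 31 when an array was left out (31 without replicate 2, 16 without replicate 3, and 19 without replicate 4), where fewer arrays have to pass. Scaling to a common median absolute deviation split it into 6 higher and 1 lower, and quantile normalization into 7 and 1. The number of gene lists called by limma's camera, 0, was 1 with position centred, 3 on replicates 1, 3 and 4, 2 on replicates 3 and 4 alone, and 2 on all 4 arrays with no sign turned. With an estimated correlation each was 0, with adjusted p = 0.573, 0.805, 0.999 and 0.571 for every called list of these settings in turn. That version of limma's camera has little power with so few arrays, so these values do not decide against the lists. The ribosomal protein shift of -0.21 became 0.46 with replicate 2 as deposited, 0.20 on all 4 arrays, 0.067 with position centred, 1.502 on replicates 1, 3 and 4, 0.78 on replicates 3 and 4 alone, 0.70 on all 4 arrays unturned, -0.41 with a dye term, -0.10 with scaling and -0.14 with quantile normalization. Leaving out an array gave -0.66 to 0.19, the last without replicate 2. The glycolysis shift passed the test at 0.79 with position centred, 1.85 on replicates 1, 3 and 4, 1.22 on replicates 3 and 4 alone and 1.00 on all 4 arrays unturned (limma's camera, adjusted p = 0.0485, 4.03e-06, 0.0264 and 0.00742). Leaving out an array gave 0.21 to 0.87. The translation factor shift of 1.07 was -0.39 with replicate 2 as deposited, 0.035 on all 4 arrays unturned, 0.51 without replicate 2, and 1.54 on replicates 1, 3 and 4, past the test there (adjusted p = 0.805 with an estimated correlation). The intron-containing shift of 1.26 was 0.56 on all 4 arrays, 0.51 with position centred, 0.25 on replicates 1, 3 and 4 and 0.15 on all 4 unturned. The amino acid shift of -0.33 was 0.49 with replicate 2 as deposited, 0.10 on all 4 arrays, 0.21 on replicates 1, 3 and 4, 0.70 on all 4 unturned, and -0.68 to 0.12 when an array was left out, the last without replicate 2. The cell wall shift of -0.60 was 0.25 on all 4 arrays and 0.38 on replicates 1, 3 and 4, and -1.28 to -0.054 without replicates 2 and 4. Of the 23 named genes with a fit, 22 were chosen for 1 sign on all 3 arrays, which fixes the sign of 132 of their values under other settings. Of the other 155 values 146 kept their sign. Most of these values come from settings that reuse arrays on which 1 sign was required, so this count is no measure of robustness. As no setting called a gene, the threshold adds nothing. The other 9 were PCL8 (0.61), RPP1A (0.25) and NUP53 (-0.055) with replicate 2 as deposited, RPP1A with no centring (0.18), HIS3 without replicate 3 (-0.10, and up to 1.09 without replicate 2), and CWC21 (-0.10), RPS17A (0.34), PCL8 (0.39) and RPP1A (0.16) on all 4 arrays unturned. Apart from the number of arrays, the cause was not tested. The filter on dim spots was not run, because the files give no intensities, and how far signals stood above background is unknown. Each ratio already pairs the 2 precipitates of an array, and no further block was fitted.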

Other observations

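Several gene groups lay near or below the array median, and many of their medians moved when runs of 400 spots were centred, an alternative chosen after the data were seen. Splicing factor genes had deposited medians of -0.41 (44 genes), -0.41 (4 genes), -0.45 (19 genes) and -0.44 (17 genes) on replicates 1 to 4, above 4.67%, 33.2%, 9.88% and 10.7% of random lists. With runs centred these were -0.18, -0.10, -0.14 and -0.31. Mitochondrial ribosomal protein genes had -0.42 (55 genes), -0.42 (3 genes), 0.22 (29 genes) and -0.33 (32 genes), and with runs centred -0.11, -0.053, -0.26 and -0.40. Ribosome biogenesis genes had 0.24 (57 genes) on replicate 1, a deposited median of -2.14 (5 genes, above 0.625% of random lists) on replicate 2, -0.60 (34 genes, above 1.28%) on replicate 3 and 0.11 (33 genes) on replicate 4. With runs centred they had 0.19, -0.58 (above 25.1%), -0.30 (above 6.2%) and -0.23. Nucleoporin genes had -0.28 (23 genes), -0.43 (3 genes, as deposited), 0.05 (11 genes) and -0.28 (16 genes), and with runs centred -0.32, -0.52, 0.42 and -0.36.

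On replicates 1, 3 and 4, chaperone genes had medians of 0.28, 0.65 and 0.12 (0.46, 0.28 and -0.10 with runs centred), nuclear-encoded oxidative phosphorylation genes 0.39, -0.09 and 0.10 (0.22, 0.13 and 0.27), and amino acid biosynthesis genes 0.29, 0.10 and 0.19 (0.27, 0.34 and 0). Environmental stress response genes had 0.07, -0.45 and -0.04 (0.11, -0.015 and 0.032), and RNA polymerase subunit genes 0.28, -0.25 and -0.03 (0.10, -0.42 and -0.20). Genes of meiosis and sporulation had -0.17 (22 genes), 0.60 (11 genes) and 0.59 (9 genes), and with runs centred -0.55, 0.18 and 0.45. Core histone genes had 0.35 (8 genes, above 71.9% of random lists) on replicate 1 and -0.98 (6 genes) on replicate 3, which became 1.51 (above 98.2%) and -0.26 with runs centred. Genes used by MATa cells had 0.11 on replicate 1 (6 genes), and those used by MATalpha cells -0.69 (4 genes, above 15.4% of random lists), or -0.14 and -1.28 (above 1.06%) with runs centred. The strain and plasmid marker genes had 0.72 (8 genes), 1.48 (3 genes) and 1.06 (5 genes), above 87.6%, 88.3% and 93.6% of random lists, and with runs centred 1.10, 0.45 and 0.027, above 94.99%, 74.6% and 58.3%.

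Of the lists ranked, 3 of 22 on replicate 3 lay above the middle 95% of random lists and 1 below it, or 3 and 0 with runs centred. On replicate 4, 2 of 20 lay above and 0 below with either values. On replicate 2, as deposited, 1 of 15 lay above and 1 below, and with runs centred 0 lay above and 2 below, translation factors (-2.01, above 0.505% of random lists) and oxidative phosphorylation (-1.42, above 1.69%). Of the 25 highest genes of replicate 1, 9 had values on replicates 3 and 4, of which 5 lay above the median on both and 1 below on both, against 242 of 725 genes (33.4%) above on both. The highest, the potassium transporter gene TRK1, had 5.69 there and -7.49 on replicate 4, and the next, the cell wall protein gene CIS3, had 5.59 there and 2.34 (sign turned), -1.86 and 0.56 on replicates 2, 3 and 4.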
